A study of Drosophila melanogaster with 6 samples.

How the data were processed

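Proventriculus RNA, taken from the valve-like organ between the foregut and midgut of Drosophila melanogaster larvae at instar 3, was measured on 6 Affymetrix Drosophila 2.0 expression arrays. The strain carried a hairy-Gal4 driver and a UAS-neoGFP transgene. The labels put 2 arrays in an unchallenged group, 2 in a group challenged with the aminoglycoside G418, and 1 array each in F3 unchallenged larvae without and with past exposure of the F1 generation. Nothing in the labels says whether the 2 arrays of a group came from separate dissections, so a p-value measures only the spread between these arrays, which may be technical.

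The deposited values are log2 expression values that the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of a probe set. The software version and whether all 6 arrays were normalized together are not given in the sources used here. The deposited table held 18952 probe sets, of which 183 control probe sets were left out and 18769 were tested. RMA compresses small differences between dim probe sets, and array values have no count or depth, so the number of arrays limits the precision.

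Probe sets were named through the array's annotation table, with symbols updated through the gene identifiers of a RefSeq gene table (assembly Release 6). In total 13647 probe sets had 1 gene symbol, 402 had several and 4720 were unnamed here. The named probe sets stood for 11982 genes, and 103 of them kept the older symbol because their gene identifier was not matched. A gene stood for its probe set with the highest mean over the 6 arrays, and a probe set with several symbols named no gene.

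G418 and unchallenged arrays were compared with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3), 2 arrays against 2, with Benjamini-Hochberg adjustment over 18769 probe sets and a threshold of 0.05. An exact permutation test of 2 against 2 cannot give a two-sided p under 0.333. Before the data were examined, 31 gene lists were fixed from knowledge of the tissue and treatment. Each was tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 lists, beside camera with an estimated correlation and fry. Members past the threshold were counted over all probe sets and adjusted over the list alone.

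The F3 arrays have no replicate and were not tested. Their log2 difference was described by counts of probe sets at or beyond 2-fold, beside the same counts for replicate arrays. A list's median difference was set against 10000 random lists of the same size, matched on mean expression in 20 bins. G418 changes and F3 differences share no array and were correlated across genes, which are not independent replicates.

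The rule for named genes was fixed at the same time. For G418 it took up to 12 genes in each direction with the largest change among those past the threshold with both G418 arrays beyond both unchallenged arrays. Remaining places went to genes with the smallest unadjusted p among those changed at least 1.5-fold with both arrays beyond both, given as values that did not pass. Up to 4 members with the smallest p were named per described list, together with every Polycomb member at an unadjusted p under 0.05 and Pc, E(z), Psc, ph-p and hairy whatever their values. For F3 it took the 8 genes with the largest difference in each direction among probe sets at or above the median mean. ph-p was not read by a probe set with 1 symbol and is not analysed here. Other genes are named as chosen after their values were seen.

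The test was checked on simulated data of the same 18769 probe sets, with the spread that limma fitted and 50 probe sets changed at each size. At a log2 change of 1 it called 0 of 50, at 2 it called 26, at 4 it called 43 and at 6 it called 45, with 7 false calls. On simulated lists of 20 independent genes, camera with the preset correlation called 20 of 20 lists shifted by 0.5 on the log2 scale and 1 unshifted list, and with an estimated correlation it called 0. Alternatives covered the replicate block, the variance prior, filters on dim probe sets, normalization, the choice of probe set, thresholds and leaving out each array.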

Results

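Expression in the larval proventriculus was measured on 6 arrays, to compare larvae under a toxic challenge with unchallenged larvae and F3 larvae with and without past exposure of the F1 generation. The challenge was G418, an aminoglycoside that is toxic to eukaryotic cells and is inactivated by the product of a neomycin resistance gene. Array medians lay between 4.91 and 5.02 on the log2 scale. Upper quartiles differed more, from 7.78 on G418 replicate 1 to 8.10 on unchallenged replicate 2. Across probe sets, Pearson's r was 0.972 between the 2 unchallenged arrays, 0.983 between the 2 G418 arrays and 0.992 between the F3 arrays.

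The arrays differed in genes listed as markers of other tissues. What lies behind these differences was not tested here, and the labels give the larval stage only as instar 3. Among salivary glue genes, Sgs3 was at 8.70 on unchallenged replicate 1 and 13.03 on unchallenged replicate 2, against 14.43 and 13.72 on the G418 arrays and 8.18 and 8.26 on the F3 arrays without and with past exposure. Some nervous tissue genes were high on unchallenged replicate 2 alone, where fne was at 9.69 and the glial factor repo at 7.42. On the other 5 arrays fne lay at or below 3.92 and repo at or below 3.49. Others differed less: brp was at 6.05 on unchallenged replicate 2 and between 5.17 and 5.75 on the other arrays. Over the 11 measured nervous tissue markers the median was 0.76 higher on unchallenged replicate 2 than on replicate 1. The fat body storage protein gene Lsp2 lay between 13.44 and 14.30 on the first 4 arrays, at 8.95 on the F3 array without past exposure and at 12.87 on the one with it. Fat body markers as a list were lower on unchallenged replicate 2 than on replicate 1, with a median log2 difference of -1.28 and Fbp2 at 11.36 and 13.75. The 3' to 5' signal gap of the Act5C control probe sets was 2.40 on unchallenged replicate 1 and between 1.63 and 1.86 on the other arrays.

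**Figure D1:**
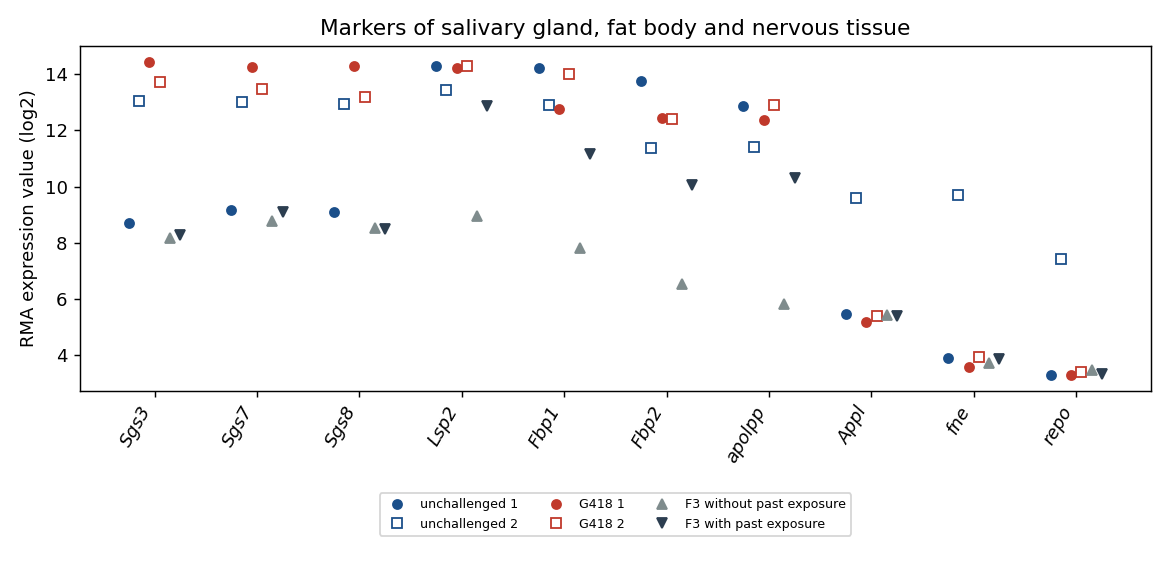
RMA expression value (log2) of markers of salivary gland, fat body and nervous tissue on each of the 6 arrays, 1 point per array. Sgs3 stood at 8.70 and 13.03 on the 2 unchallenged arrays, and repo at 7.42 on unchallenged replicate 2 alone.

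The first comparison asked which RNAs differ between G418-challenged and unchallenged larvae. Glutathione S-transferases conjugate foreign compounds to glutathione. Of 11 measured genes of their GstD cluster, 10 had a positive log2 change with G418, from 0.27 for GstD1 upward, and GstD3 was at -0.06. GstD2 was 38.9-fold higher, from 6.76 ± 0.20 to 12.04 ± 0.14 (SD, n = 2 arrays each), and GstD5 was 8.79-fold higher, from 6.50 ± 0.10 to 9.64 ± 0.17 (SD, n = 2). GstD4 was 12.3-fold higher, with a log2 change of 3.62 ± 0.45 (SE). None of these passed the test over all probe sets: limma called 0 probe sets higher and 0 lower. It gave 664 of 18769 an unadjusted p under 0.05, where chance gives 938. With the replicate number as a block that count was 2187, with 0 calls, though the labels do not say that a number pairs arrays. The lowest adjusted p in limma was 0.0904, for GstD2.

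The other genes among the 12 named as higher were Rdh1, CG11893, CG6996, CG33127, Nazo, CG32195, CG12766, CG17930 and CG5550. CG11893 was 13.6-fold higher, with a log2 change of 3.76 ± 0.34 (SE), and CG5550 was 13.8-fold higher, with 3.79 ± 0.46. Rdh1 was 7.09-fold higher and Nazo 2.58-fold higher. Limma's adjusted p was 0.278 for GstD5, 0.495 for Rdh1 and 0.788 for the other genes of this group from CG11893 to GstD4.

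**Figure D2:**
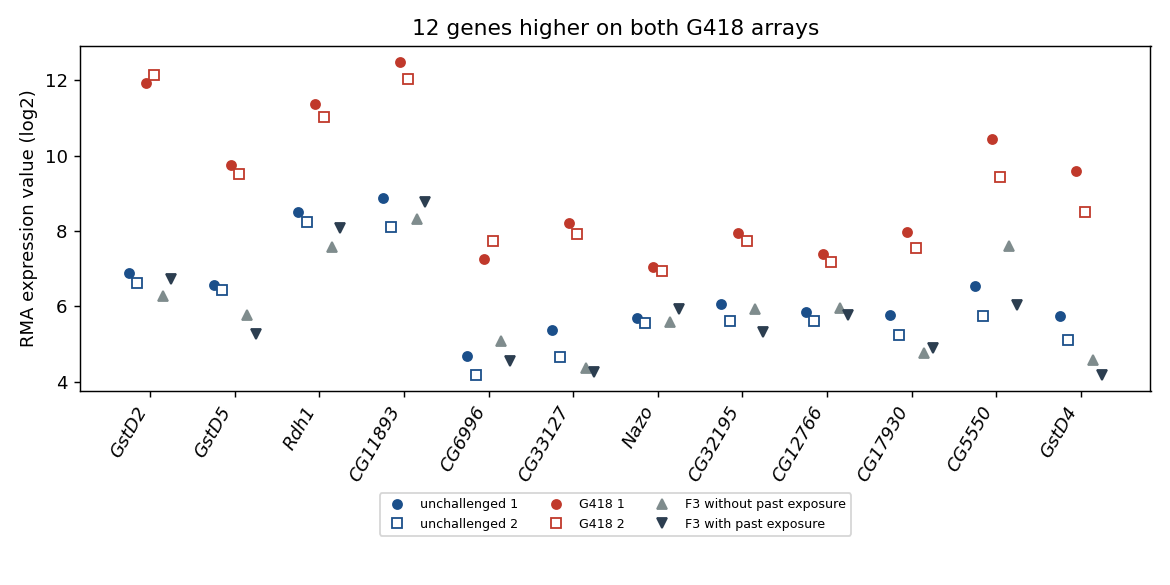
RMA expression value (log2) of the 12 genes named as higher with G418, 1 point per array. GstD2 stood at 11.94 and 12.14 on the G418 arrays and between 6.28 and 6.90 on the other 4.

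The 12 genes named as lower changed less. CG13002 was 5.43-fold lower with G418, from 11.53 ± 0.12 to 9.09 ± 0.01 (SD, n = 2), with an adjusted p of 0.318 in limma. Obp49a, an odorant-binding protein gene, was 2.99-fold lower, CG9098 2.99-fold, CG9801 2.42-fold and CG15822 2.37-fold. The flight muscle actin gene Act88F was 2.26-fold lower, edin, an immune-responsive gene, 2.21-fold, the C/EBP transcription factor gene slbo 2.15-fold and CG15120 2.11-fold. CG17738, the polarity adaptor gene veli and CG6012 were 1.90-fold, 1.86-fold and 1.76-fold lower. All but CG13002 had an adjusted p of 0.788 in limma. Of 11982 genes, 4598 (38.4%) had both G418 arrays beyond both unchallenged arrays, where chance gives 33.3%.

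Which array was left out changed the count of calls. Without unchallenged replicate 1, limma called 251 probe sets, 59 higher and 192 lower, against unchallenged replicate 2 alone, the array with the high nervous tissue markers. Without unchallenged replicate 2 it called 4, all lower: CG15155, CG11892, CG14957 and CG10514, named after their values were seen, which stood between 9.43 and 10.77 on unchallenged replicate 1 and between 3.39 and 3.92 on unchallenged replicate 2.

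Lists of detoxification genes were called as shifted up by camera with the preset correlation. Of 34 measured glutathione S-transferases 22 were higher with G418, of which 10 were among the 11 measured GstD genes. Over all probe sets 0 members passed. Adjusted over the list alone 7 passed, all of them GstD genes: GstD2, GstD4, GstD5, GstD6, GstD7, GstD8 and GstD9. The list's median log2 change was 0.15, with an adjusted p of 1.3e-05 in camera and adjusted p = 0.795 with an estimated correlation. The genes GstD1 to GstD10 lie side by side on chromosome 3R and resemble each other in sequence, so probes may not fully separate them. Camera counted them as separate genes. Of 81 cytochrome P450 genes 64 were higher, with a median of 0.28 (camera adjusted p = 4.35e-07, and adjusted p = 0.795 with an estimated correlation). Fat body markers were not called (camera adjusted p = 0.298), with 5 members higher and 3 lower. Their median was 0.40 with G418 (percentile 99.97 of matched random lists, which draw genes independently). Between unchallenged replicates 2 and 1 the medians differed by -0.47 for P450s and -1.28 for fat body markers. Between G418 replicate 2 and unchallenged replicate 2 they differed by 0.53 and 0.97. Between G418 replicate 1 and unchallenged replicate 1 they differed by 0.05 and -0.41. Cyp4p2 was at 1.49 ± 0.31 (SE), Cyp6a2, known from insecticide resistance, at 1.37 ± 0.35, Cyp6d4 at 0.90 ± 0.16 and Cyp12c1 at 0.85 ± 0.26. Of 35 UDP-glycosyltransferase genes 28 were higher, with a median of 0.19 (camera adjusted p = 3.01e-04, and adjusted p = 0.795 with an estimated correlation). Ugt37A2 was at 3.13 ± 0.68 while Ugt37D1 went the other way, from 11.26 and 11.38 on the unchallenged arrays to 8.43 and 10.21 on the G418 arrays. For both lists 0 members passed over all probe sets and 0 adjusted over the list alone. Without unchallenged replicate 2 the P450 median was 0.04 (camera adjusted p = 0.185), and without unchallenged replicate 1 it was 0.47. The glutathione S-transferase median was 0.33 without unchallenged replicate 1 and 0.23 without G418 replicate 2, and the UDP-glycosyltransferase median 0.32 and 0.35. Over probe sets at or above the median mean the UDP-glycosyltransferase median was 0.69, and after a further quantile normalization 0.11, with the call kept in both. For the pair G418 replicate 2 and unchallenged replicate 1, chosen after the data were seen, the medians were 0.02 for glutathione S-transferases, 0.01 for UDP-glycosyltransferases and -0.0011 for P450s.

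Polycomb group genes, which keep developmental genes silent through chromatin, were lower as a group. All 16 measured members had a negative log2 change, and 9 had both G418 arrays below both unchallenged arrays. The median log2 change was -0.46 (camera adjusted p = 1.1e-04, and adjusted p = 0.795 with an estimated correlation), and 0 members passed over all probe sets or adjusted over the list alone. Psc was at -0.86 ± 0.53 (SE), with 6.60 and 7.49 on unchallenged replicates 1 and 2 and 5.58 and 6.78 on G418 replicates 1 and 2. Its G418 replicate 2 value thus lay above that of unchallenged replicate 1. Pc was at -0.61 ± 0.27, Asx at -0.53 ± 0.21, Su(z)12 at -0.53 ± 0.22, Jarid2 at -0.44 ± 0.17 and E(z) at -0.26 ± 0.15. No member had an unadjusted p under 0.05. Without unchallenged replicate 2 the median was -0.27 (camera adjusted p = 0.0352), without G418 replicate 1 it was also -0.27 (0.00732) and without G418 replicate 2 it was -0.75. The list's median differed by 0.33 between the 2 unchallenged arrays (replicate 2 above 1) and by 0.42 between the 2 G418 arrays (replicate 2 above 1). For the pair G418 replicate 2 and unchallenged replicate 1, chosen after the data were seen, it was -0.10. hairy, whose driver the strain carries and whose symbol is hry here, was at 0.12 ± 0.25.

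**Figure D3:**
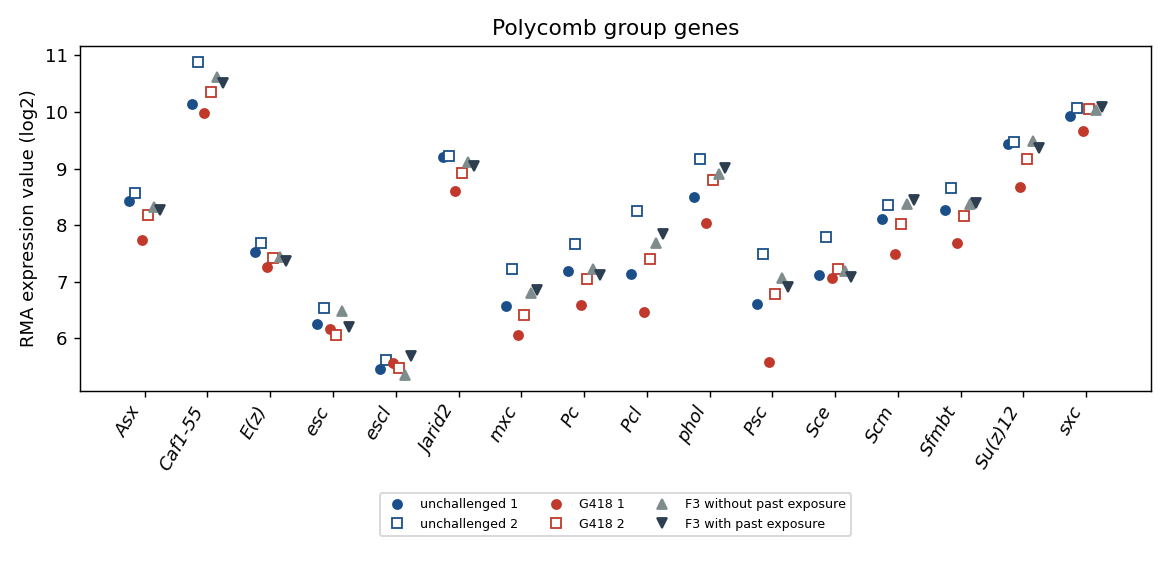
RMA expression value (log2) of the 16 measured Polycomb group genes, 1 point per array. Pc stood at 7.18 and 7.66 on the unchallenged arrays, at 6.58 and 7.05 on the G418 arrays and at 7.23 and 7.12 on the F3 arrays without and with past exposure.

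Other chromatin, patterning and growth lists were also lower, and salivary markers higher. All 21 cell cycle and DNA replication genes were lower with G418, with a median of -0.61 (camera adjusted p = 4.4e-06); Orc1 was at -0.74 ± 0.23 (SE), dup at -0.69 ± 0.23 and fzr at -0.60 ± 0.19. Of 14 Trithorax group genes 13 were lower (median -0.44, camera adjusted p = 0.00114), with osa at -0.62 ± 0.24 and lolal at -0.50 ± 0.17. Of 28 foregut and gut patterning regulators 22 were lower (median -0.36, adjusted p = 0.00416), among them sob at -0.58 ± 0.22 and bowl at -0.50 ± 0.22, and of 33 other segmentation and selector regulators 27 were lower (median -0.31, adjusted p = 0.00164). All 7 heat shock and chaperone genes were lower (median -0.40, adjusted p = 0.00409), with Hsp26 at -1.42 ± 0.51. The lists of ribosome biogenesis (median -0.30, adjusted p = 0.00724), JNK and cell death (-0.20, 0.0112) and midgut stem and enteroendocrine markers (-0.74, 0.0425) were lower, and those of midgut digestive enzymes (0.14, 0.0135) and vacuolar ATPase subunits (0.12, 0.0489) higher. All 14 salivary gland markers were higher, with a median of 2.77 (adjusted p = 4.23e-06). Each of these lists had an adjusted p = 0.795 with an estimated correlation, and 0 members past the threshold over all probe sets or adjusted over the list alone. Against random lists matched on mean expression, the ribosome biogenesis median lay inside the matched range of -0.31 to 0.05 (percentile 3.065). The JNK and cell death median lay inside its range of -0.26 to 0.13 (percentile 6.99). By this measure neither list stood apart from genes of like expression. The other lists called in this paragraph lay outside their ranges. Random lists draw genes independently, so these ranges may be too narrow. Several calls of this paragraph were lost with 1 array left out, in camera with the preset correlation. Without unchallenged replicate 2 they were Trithorax (median -0.15, adjusted p = 0.188), ribosome biogenesis (-0.12, 0.606), JNK and cell death (-0.13, 0.132), midgut stem and enteroendocrine markers (-0.10, 0.257), vacuolar ATPase (0.06, 0.296) and midgut digestive enzymes, which turned to -0.09 (0.436). Without G418 replicate 1 they were foregut patterning (-0.14, 0.115), heat shock (-0.35, 0.0527), ribosome biogenesis (-0.09, 0.168), JNK and cell death (-0.20, 0.0557), vacuolar ATPase (0.02, 0.421) and midgut digestive enzymes, which turned to -0.02 (0.745). Without G418 replicate 2 they were other segmentation regulators (-0.46, 0.0805) and midgut stem markers (-1.01, 0.184), and without unchallenged replicate 1 vacuolar ATPase (0.17, 0.107). Other settings ended calls too. Over probe sets at or above the median mean these were other segmentation regulators (median -0.31, adjusted p = 0.558) and ribosome biogenesis (-0.30, 0.0879). They were also JNK and cell death (-0.21, 0.114), midgut stem markers (-0.86, 0.114) and vacuolar ATPase (0.06, 0.153). After a further quantile normalization they were midgut digestive enzymes (0.0875) and vacuolar ATPase (0.207), after median centring vacuolar ATPase (0.0586), and with the mean of all probe sets of a gene JNK and cell death (0.0961). For G418 replicate 2 minus unchallenged replicate 1, chosen after the data were seen, the medians turned to 0.00805 for cell cycle genes, 0.05 for Trithorax, 0.07 for ribosome biogenesis, -0.145 for midgut digestive enzymes and -0.03 for vacuolar ATPase. With 1 array left out, other medians kept their call and moved by over 1.5 times. Cell cycle genes were at -0.27 without unchallenged replicate 2 and -0.98 without unchallenged replicate 1, and salivary markers at 1.45 without G418 replicate 1. Other segmentation regulators were at -0.13 without unchallenged replicate 2, and heat shock genes at -0.27. Without unchallenged replicate 1 Trithorax genes were at -0.71, other segmentation regulators at -0.62, ribosome biogenesis at -0.51, JNK and cell death at -0.32, midgut stem markers at -1.28 and midgut digestive enzymes at 0.32. Without G418 replicate 1 Trithorax genes were at -0.24 and midgut stem markers at -0.43, and without G418 replicate 2 foregut patterning was at -0.55 and midgut digestive enzymes at 0.22.

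In all, camera with the preset correlation called 15 of 31 lists, 6 up and 9 down. With an estimated correlation it called 0, and fry called 0, with a lowest adjusted p of 0.705. Camera with an estimated correlation also called 0 of 20 shifted lists in the simulated data, so its 0 here decides nothing. Fry was not simulated. The simulated genes were independent, so false calls at the preset correlation were not measured for genes that vary together. The other 16 lists, among them Hox genes, antimicrobial peptides and immune recognition, ribosomal proteins, proteasome subunits, ecdysone response and the unfolded protein response, had camera adjusted p-values from 0.148 to 0.927. The median of the nervous tissue markers was 0.76 higher on unchallenged replicate 2 than on replicate 1, and that of the cell cycle list 0.71 higher.

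The second comparison set F3 larvae whose F1 ancestors had been exposed against F3 larvae without past exposure, with 1 array each and no replicate check. Genes of the fat body were higher with past exposure than without it. The lipophorin precursor gene apolpp differed by 4.51 on the log2 scale and Lsp2 by 3.92. Fbp2 differed by 3.53, Fbp1 by 3.34 and the clotting gene fon by 3.42. They were followed by CG12116 at 3.31, Acbp4 at 3.07 and CG34166 at 2.89. Even with past exposure, all 8 stood below their values on every unchallenged and G418 array. For example, apolpp was at 5.81 without and 10.32 with past exposure, and between 11.43 and 12.89 on the unchallenged and G418 arrays. The mucin gene Muc11A was lower, with a log2 difference of -6.69, as were CG11892 at -6.14, CG9259 at -6.02, CG15155 at -5.74, CG10514 at -5.43, CG10513 at -5.11, CG16727 at -4.71 and CG17752 at -4.52. All 8 of these lower genes were also higher on unchallenged replicate 1 than on unchallenged replicate 2, for example Muc11A at 8.34 and 4.46.

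In total 70 probe sets were at least 2-fold higher and 151 at least 2-fold lower with past exposure. The 2 unchallenged arrays differed at least 2-fold at 1293 probe sets and the 2 G418 arrays at 645, so the 221 of the F3 pair were fewer than within either replicated group. Of these 221 probe sets, 128 (57.9%) also differed at least 2-fold between the unchallenged arrays, against 6.89% of all probe sets.

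By list, 8 fat body markers had a median F3 difference of 1.999 on the log2 scale (percentile 100 among the 10000 matched random lists), with 7 higher and 1, Lip3, lower at -2.15. Haemocyte and lymph gland markers had a median of 0.45 and muscle markers of 0.34, both also at percentile 100, with PPO1, a prophenoloxidase gene, at 1.92 and sls, the muscle titin gene, at 1.44. Mitochondrial ribosomal protein genes had a median of 0.12 (percentile 99.96). Midgut digestive enzymes had a median of -0.16 (percentile 0), proteasome subunits of -0.12 (0.02), Malpighian tubule markers of -0.25 (0.02), heat shock and chaperone genes of -0.35 (0.19), the ecdysone response of -0.12 (0.40), UDP-glycosyltransferases of -0.09 (0.51) and sex and gonad markers of -0.13 (1.52). These 11 of 31 lists lay outside the central 95% of matched lists, where lists of independently drawn genes would give 1.55. Genes of a list can vary together, so 1.55 is not the number to expect between 2 single arrays. For 3 of the 11, fat body, muscle and Malpighian tubule markers, the F3 median was farther from 0 than that between the 2 arrays of either replicated group. For the other 8 it was not. Of the Malpighian tubule markers, however, only 4 of 12 lay at or above the array median on all 6 arrays. Their median for G418 replicate 2 minus unchallenged replicate 1 was -0.26, about as large as in F3. Between unchallenged replicates 2 and 1 the medians were -0.93 for haemocyte markers, -0.61 for midgut digestive enzymes, 0.48 for the ecdysone response, 0.26 for mitochondrial ribosomal proteins and -0.22 for UDP-glycosyltransferases. Polycomb group genes had a median of -0.05 (percentile 10.5) and glutathione S-transferases of 0.07 (percentile 91.7).

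The 2 comparisons were then joined, to ask whether genes that differed with G418 differed in F3. Of the 12 genes named as lower with G418, 11 were also lower with past exposure, with Obp49a at -1.66, slbo at -1.44, CG6012 at -1.22, CG15120 at -0.97, CG9801 at -0.85 and CG13002 at -0.84; Act88F was at 0.46. Matched random sets of 12 genes held a median of 5 lower genes, and 14 of 10000 held 11 or more. These sets draw genes independently, so 14 of 10000 is not a p-value for genes that vary together on 2 single arrays. Of the 12 genes named as higher, 5 were higher with past exposure, against a matched median of 7; GstD2 was at 0.44, GstD4 at -0.40 and GstD5 at -0.51.

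Across 11982 genes, the G418 change and the F3 difference correlated with Pearson's r = 0.178 and Spearman's rho = 0.135. The value was r = 0.203 for the replicate 1 arrays and 0.0934 for the replicate 2 arrays. For the crossed pairs, added after the data were seen, it was 0.287 for G418 replicate 2 minus unchallenged replicate 1 and 0.0701 for G418 replicate 1 minus unchallenged replicate 2. Spearman's rho for these 4 pairs lay between 0.0981 and 0.111. As background, the F3 difference correlated with the difference between the unchallenged arrays at r = 0.0790 (rho = -0.0423) and with that between the G418 arrays at r = -0.0036 (rho = -0.0366). No gene was called in the G418 test, so the share of called genes with the same sign could not be given.

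**Figure D4:**
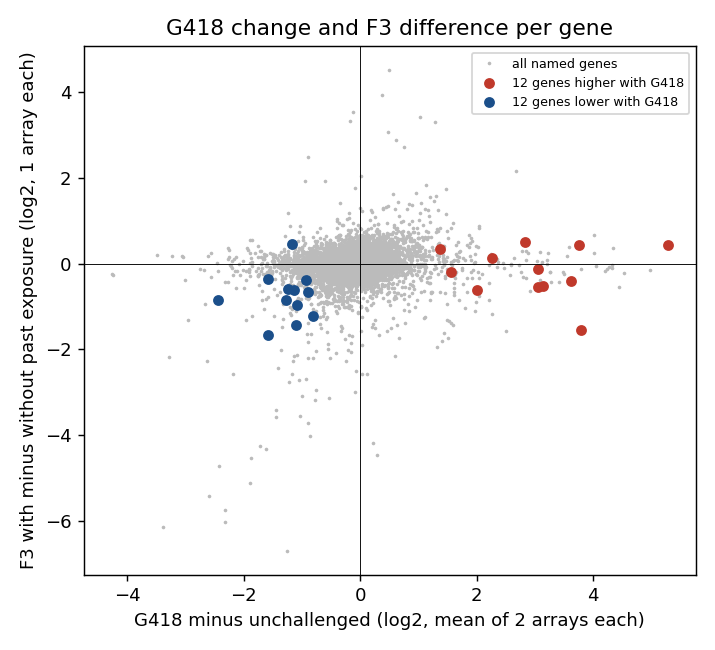
Log2 change with G418 (x axis, mean of 2 arrays minus mean of 2) against the log2 difference between the F3 arrays with and without past exposure (y axis, 1 array each), 1 point per gene for 11982 genes. Of the 12 genes lower with G418, 11 lay below 0 on the y axis, and of the 12 higher ones 5 lay above 0.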

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

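The Polycomb median without unchallenged replicate 2 was planned in advance; its matched range and the other tests in this part were chosen only after the result was seen. Among the 100 control probe sets whose ID begins with AFFX-Dm, left out of the comparisons, 3 were at least 1.5-fold higher with G418, at an unadjusted p under 0.05 and with both G418 arrays above both unchallenged arrays. AFFX-Dm-M62653-1_s_at was at 8.19 and 8.31 on the unchallenged arrays and at 9.91 and 10.11 on the G418 arrays, a log2 change of 1.76 ± 0.15 (SE), with 9.88 and 9.47 on the F3 arrays without and with past exposure. AFFX-Dm-AF292560-1_s_at had a log2 change of 1.52 ± 0.18 and stood at 9.98 and 9.75 on the F3 arrays, and AFFX-Dm-U57609-2_s_at of 0.835 ± 0.18, at 11.87 and 11.65. All 3 were thus higher on the F3 arrays, from larvae not given G418, than on both unchallenged arrays. In a limma fit that kept the control probe sets, the adjusted p was 0.790 for each. The tables used here do not pair these probe sets with genes, so whether any of them reads the transgene that the strain carries, rather than a fly gene, is not known here, and what these changes measure is left open.

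The Polycomb list was lower with G418. Whether tissue on unchallenged replicate 2 alone lies behind it is not decided. Without that array the median was -0.27, just below the central 95% of matched random lists (-0.24 to 0.06), with 13 of 16 members lower. The random lists draw genes independently, so this range may be too narrow for genes that vary together. The G418 arrays were also unlike: against unchallenged replicate 1 the median was -0.55 for G418 replicate 1 and -0.098 for G418 replicate 2. Whether uneven amounts of other tissue on unchallenged replicate 2 and G418 replicate 1 together lie behind it cannot be told apart. G418 replicate 2 minus unchallenged replicate 1 gave a median of -0.098, just inside the matched range of -0.11 to 0.14, but for this list the pair leaves out the higher unchallenged array and the lower G418 array, so a small value follows from the choice. Those 2 arrays carried the highest nervous tissue and early salivary markers, with fne at 9.69 and ng3 at 12.25; 3 of 11 nervous tissue markers and 8 of 14 salivary markers lay at or above the array median on all 6 arrays. A lowering by G418 stays open, untested.

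The 12 genes named as higher with G418 did not follow the salivary gland markers. G418 replicate 2 and unchallenged replicate 2 both held salivary markers, which differed by a median of 0.38, while the 12 genes differed by a median of 3.18 (range 1.37 to 5.52). A high value was partly fixed by the choice of genes with both G418 arrays above both unchallenged arrays. The choice of small p also left out genes far apart between the unchallenged arrays, such as Sgs3. The values therefore speak for these 12 genes only and do not test carried-over salivary tissue for other higher genes. Whether probes shared between paralogs spread one gene's signal over the GstD cluster cannot be told apart without probe sequences: 10 of 11 measured GstD genes were higher and 1, GstD3, was at -0.06. A response to G418 stays open as a hypothesis.

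Genes lower with G418 were also lower with past exposure: of the 100 with the smallest p, 77 were lower (median F3 difference -0.37), where matched random sets held 36 to 56 and 0 of 10000 held as many. Of the 100 higher genes with the smallest p, 60 were higher, inside the matched range of 45 to 64. Their median F3 difference of 0.12 nevertheless lay at percentile 99.98 of matched sets. Matched sets draw genes independently, so these ranges may be too narrow for genes that vary together. Tissue on either unchallenged array cannot be told apart from an effect shared by both comparisons. Of 100 lower genes chosen without unchallenged replicate 1, 53 were lower in F3 (matched range 39 to 59), and of 100 chosen without replicate 2, 83 were (36 to 56), but these shared 2 and 23 genes with the original 100, below a limit of 50 set after the values were seen; 26 of the original 100 were higher on unchallenged replicate 1 than on replicate 2, which decides nothing because genes far apart between these arrays seldom had a small p. An effect of past exposure and any other difference between 2 single arrays stay open too.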

How the results depend on the processing

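Alternatives were planned in advance, and those chosen after seeing the data were the control probe sets kept in, the single pair of arrays and the 100 genes of smallest p in each direction. Limma's count of 0 probe sets was 1 (GstD2) with trend and robust options and 1 at an adjusted p under 0.10, and 0 to 251 with an array left out, where the lone array of a group is assumed to vary like the other group. Counts stayed at 0 under the replicate block, both filters, 3 normalizations, 1 probe set per gene, both fold floors, the 6-array fit and with control probe sets kept. With the replicate block, 2187 probe sets had an unadjusted p under 0.05 and 15 lists were called, the same 15; deviations of same-numbered arrays correlated at 0.315, and the labels do not say that a number pairs arrays. The count of 15 lists was 0 with an estimated correlation, 11 to 22 with an array left out and 10 to 15 otherwise. With an array left out, midgut digestive enzymes ranged from -0.0877 to 0.318, turning below 0 without unchallenged replicate 2 and, at -0.0207, without G418 replicate 1. For G418 replicate 2 minus unchallenged replicate 1 alone, medians turned to 0.0502 for Trithorax, -0.0011 for P450s, 0.0666 for ribosome biogenesis, 0.00805 for cell cycle, -0.145 for midgut digestive enzymes and -0.0333 for vacuolar ATPase; the cause was not tested. All 24 named genes kept their direction in every setting that tested them, which was largely fixed by their choice. With both G418 arrays beyond both unchallenged arrays, leaving out an array could not turn them. The block, variance prior, filters and 6-array fit kept the same log2 change, so only the 3 normalizations could have turned them. The lowest adjusted p in limma was 0.0132, for GstD2 with trend and robust options. The F3 count of 221 was 648 at 1.5-fold and 98 at 3-fold, by construction, and 197 to 226 otherwise. F3 lists outside the central 95% numbered 11 to 12. The correlation of 0.178 was 0.0934 without replicate 1, 0.203 without replicate 2 and 0.341 over the 100 genes of smallest p in each direction, and moved by under 0.0773 otherwise. The share of called genes was not run, as none was called.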

Other observations

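Members of the ecdysteroid kinase-like family, whose membership was listed from general knowledge after the values were seen, were among the largest increases with G418. CG11878 was 31.6-fold higher, with a log2 change of 4.98 ± 0.66 (SE), CG16898 20.2-fold higher (4.33 ± 0.63), CG31104 18.4-fold higher (4.20 ± 0.57) and CG31288 11.7-fold higher (3.55 ± 0.61). Of 44 measured members 31 were higher, 14 had an unadjusted p under 0.05, all higher, and 0 passed in limma over all probe sets. The family's median log2 change was 0.23. CG11893 and CG32195, named above as higher, belong to it, and since it was picked for such members these values are no test of the family. Family members CG10513, CG10514, CG11892 and CG9259 instead stood high on unchallenged replicate 1 and on the F3 array without past exposure alone, with CG11892 at 10.77 and 10.19 there and at or below 4.12 on the other arrays.

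Some regulators, chosen after their values were seen, had the same sign in both comparisons. The nuclear receptor gene ftz-f1 had a log2 change of 1.04 ± 0.22 (SE) with G418 and a difference of 1.42 between the F3 arrays. Eip78C, an ecdysone-induced receptor gene, was at -0.92 ± 0.41 and -1.65, and pirk, a negative regulator of the IMD immune pathway, at -0.90 ± 0.25 and -1.39. The digestive maltase genes Mal-A1 and Mal-A3 were at 2.92 ± 0.77 and 1.94 ± 0.32 with G418, and at -0.63 and -0.16 in F3. Limma's adjusted p for the G418 change was 0.788 for each of these genes.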
